A study of Drosophila melanogaster with 9 samples.

How the data were processed

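The series holds 9 RNA sequencing libraries of Drosophila melanogaster: 3 of a control with the UAS-Dube3a transgene alone, 3 of a glial line (repo-GAL4 with the transgene) and 3 of a neuronal line (elav-GAL4 with the transgene). GAL4 is a yeast transcription factor that switches on a transgene placed behind its UAS binding sites. The labels name whole brain and dissected brain as the material, while the study's design text describes pools of heads, so whether other head tissue was present is not settled by the labels. The labels do not say whether the replicates of a genotype come from separate crosses, so each p-value refers to the spread among these samples. The flies were kept at 25 degrees, RNA was extracted with TRI reagent, and libraries were run on an Ion Torrent instrument. No batch or run date is given per library.

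The deposited table holds raw counts, whole numbers with no scaling for length or depth, for 31838 RefSeq transcripts in 9 columns, all of which were used. STAR and DESeq2 are named by the authors without a role or version. The program that counted reads, the genome build, the annotation release and the handling of strand are not given in the sources used here. Of the transcripts, 31673 matched a gene in the RefSeq annotation of assembly Release 6 plus ISO1 MT, giving 15248 genes, of which 6943 had more than 1 transcript. The other 165 held 0.3% to 0.68% of the counts and were kept as entries of their own, counted among the genes below. Of these 92 were tested, and 6, 0 and 4 passed in the 3 comparisons in the order given below. Gene names and chromosome arms come from that annotation, and coordinates are not printed since the authors' build is not named.

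In para, the gene examined for this, most isoforms held nearly equal but not identical counts. Of 60 isoforms of para, 57 lay near their median, with a mean of 34.6 counts in control library 1, where the largest of the 60 held 2068. The variance to mean ratio of the 57 had a median of 1.29 over the libraries. Reads shared by isoforms of para thus appear to have been divided among them or assigned at random. Other genes were not measured in this way. Counts were summed per gene. This choice followed inspection of the table, and single transcripts were run as an alternative. Reads from stretches where genes overlap cannot be assigned, and 60 of the 162 genes chosen for naming overlap another annotated gene.

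Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, and the quasi-likelihood test with group as the only term, fitted to all 9 libraries. After the filter 11430 genes were tested and 3983 were not. Benjamini-Hochberg adjusted p under 0.05 counted as a change. The standard error of a log2 fold change is its size divided by the square root of the test's F statistic. The 3 comparisons were glial against control, neuronal against control and glial against neuronal, the last of which tests a difference between the lines and not between effects of the transgene alone. The groups, the comparisons, the tests, 28 gene lists, the rule for named genes and the main alternatives were chosen before the data were examined.

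The gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 28 lists within a comparison, beside camera with an estimated correlation and fry. Of 28 lists, 15, 12 and 19 passed in the 3 comparisons with the preset correlation. With an estimated correlation 2 passed in glial against control, glutathione S-transferases and fat body markers, and 0 in the others, where the smallest adjusted p were 0.56 and 0.057. Fry passed 12, 0 and 15 lists. It asks whether the genes of a list move on balance one way and does not compare them with other genes. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Several lists share genes: fat body markers share 8 with lipid metabolism and 5 with sex-linked markers, and synaptic vesicle release shares 6 with neuronal markers. Glial markers share 6 genes with neurotransmitter synthesis and transport, and nrv2 and zyd with the sodium-potassium pump list. The sex-linked list mixes yolk protein genes with roX genes and sex determination genes, so its median is not a measure of sex. The list members CecA1, CecB, CG3701, Sr-CII, Os9, Hop and sop were not found in the table under those names.

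Named genes were chosen by a rule. Ube3a, elav and repo were always included. For each comparison, up to 10 genes with the largest positive and 10 with the largest negative log2 fold change were taken among genes with adjusted p under 0.05, a mean of at least 20 counts over the 6 libraries compared and no overlap between the groups in CPM. For each list, up to 4 members past the threshold with the smallest p were taken, or, if none passed, up to 2 with the highest mean CPM as values. Of genes that changed in one direction in both lines, 5 per direction were taken by the smaller of the 2 changes. The text gives a part of these genes.

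Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with an exact 95% interval (Clopper-Pearson on the share of the 2 counts). Intervals and floors cover counting error only. CPM on the log scale used a prior count of 2.

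Total counts per library ranged from 35550949 to 60322417. Ribosomal RNA held 0.75% to 2.86% and the 20 most abundant genes 19.5% to 29.2% of the counts. The biological coefficient of variation was 0.31, and the lowest Pearson r of log2 CPM between libraries of one group, across genes, was 0.951. The test was tested on simulated data with these depths and this spread, with 200 changed genes among 11271. It recovered 34% of 2-fold and 79% of 4-fold changes for glial against control, with 3 unchanged genes among 116 calls. For neuronal against control it recovered 17% and 84%, with 3 among 104. Genes were drawn independently from the fitted spread, without structure shared across genes, so the number of false calls may be higher in the real libraries. The shared controls were examined with 50 simulations of unchanged groups, in which each gene was drawn independently.

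Alternatives set in advance were DESeq2 size factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 5 CPM in 3 libraries, an adjusted p of 0.01, a 2-fold minimum, the 6 compared libraries alone, a replicate block and leaving out each library. Alternatives added after the data were seen were a covariate for the gut marker level, a covariate for the yolk protein level, leaving out ribosomal RNA and yolk genes, and single transcripts. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.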

Results

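RNA of adult Drosophila melanogaster was sequenced on an Ion Torrent instrument in 9 libraries, 3 from each of 3 genotypes, to ask which transcripts change when Dube3a is overexpressed in glia or in neurons. Dube3a, listed as Ube3a in the annotation, is the fly homologue of the E3 ubiquitin ligase UBE3A. The control carried the UAS-Dube3a transgene with no driver. The glial line added repo-GAL4, which drives a UAS transgene in glia, and the neuronal line added elav-GAL4, which drives it in neurons. No library carried a driver without the transgene, so a driver's own effect was not measured apart from that of Dube3a. Total counts were 38554008, 35550949 and 37359569 in control libraries 1, 2 and 3. They were 60322417, 39205825 and 38070711 in the glial libraries and 41080491, 40461345 and 36100125 in the neuronal libraries. Log2 fold changes are given ± standard error, levels as mean CPM (counts scaled to a depth of 1e+06) ± SD, and n was 3 libraries per group throughout. Each p of a single gene is from the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment.

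Transcripts of digestive enzymes made in the gut differed between libraries of one genotype. The mean log2 CPM of 22 gut markers was 4.68, 7.56 and 3.58 in control libraries 1, 2 and 3, 8.30, 4.34 and 8 in the glial libraries, and 6.05, 7.67 and 7.78 in the neuronal libraries. The trypsin gene betaTry averaged 7200 ± 9200 CPM in the control, 10600 ± 9010 in the glial line and 11000 ± 7880 in the neuronal line. The main axis of a principal component analysis held 36% of the variance and placed control 1, control 3, glial 2 and neuronal 1, the libraries with the lowest gut level, below 0 and the other 5 above 0. The next axis held 19.6% and placed the glial libraries at 19.2, 54.6 and 30, above control (-12.4, -20.9 and 1.40) and neuronal libraries (-23.8, -25.0 and -23.2). Genotype accounted for 23.8% of the variance of the gut level (exact permutation p = 0.47 over 1680 groupings). Yolk protein genes, expressed in the female fat body, held 14.1%, 8.62% and 9.26% of the counts in control libraries 1, 2 and 3. They held 4.16%, 13.53% and 12.48% in the glial libraries and 6.34%, 7.24% and 7.08% in the neuronal libraries. All 3 neuronal libraries thus lay below all 3 control libraries, so the yolk level cannot be parted from genotype in that comparison.

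Ube3a, on chromosome arm 3L, was higher in both driver lines than in the control. It averaged 34.6 ± 4.58 CPM in the control, 209 ± 17.5 CPM in the glial line and 70.4 ± 7.95 CPM in the neuronal line. In the glial line it rose 6.04-fold (log2 fold change 2.59 ± 0.15, adjusted p = 8.4e-05). In the neuronal line it rose 2.03-fold (1.02 ± 0.14, adjusted p = 0.014), and the glial line exceeded the neuronal line 2.97-fold (1.57 ± 0.14, adjusted p = 0.00063). All 3 libraries of each driver line lay above all 3 control libraries. The neuronal call was lost without control 1 (0.94, adjusted p = 0.0833), control 2 (0.99, 0.0647), neuronal 1 (1, 0.072) or neuronal 3 (0.96, 0.0878), and with scaling by library totals (1.08, 0.0839) or a replicate block (1.02, 0.0501). The counts do not separate transcripts of the transgene from those of the native gene. The white gene w, whose mini-white form commonly marks fly transgenes, rose by 3.06 ± 0.13 in the glial line (20.7 ± 1.13 to 172 ± 17.8 CPM, adjusted p = 1.4e-05) and by 1.53 ± 0.13 in the neuronal line (59.6 ± 6.40 CPM, adjusted p = 0.0017). The gene elav, a neuronal RNA-binding protein gene at the neuronal driver's locus, gave 0.15 ± 0.10 (adjusted p = 0.49) and 0.48 ± 0.10 (adjusted p = 0.09) in the glial and neuronal lines. The glial transcription factor gene repo gave -0.42 ± 0.21 (adjusted p = 0.3) and -0.06 ± 0.21 (adjusted p = 0.93), and the sign of the neuronal value turned without neuronal 1 (0.06) or neuronal 3 (0.05).

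**Figure D1:**
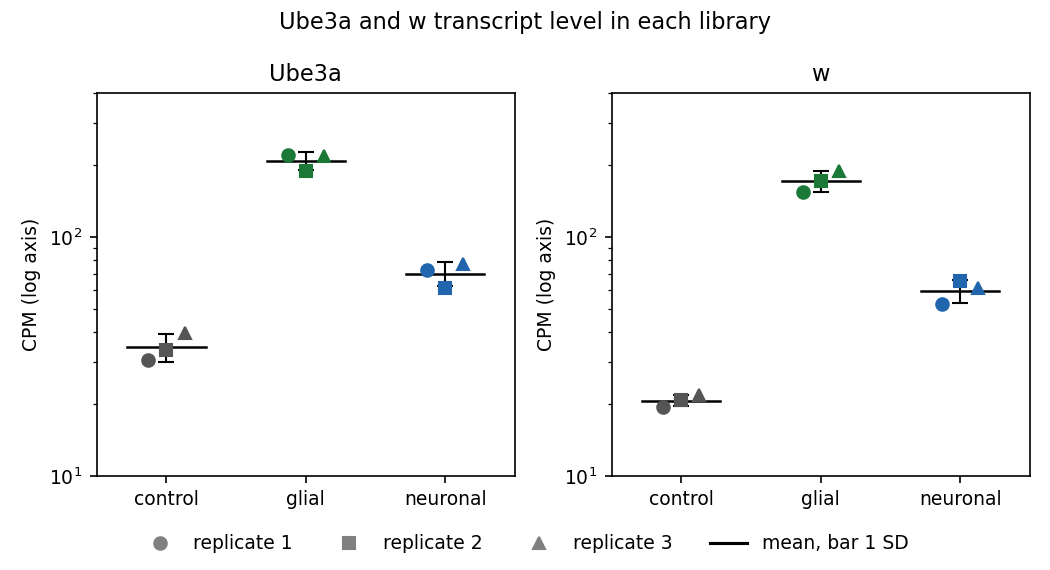
Ube3a and w in CPM (log axis) in each of the 9 libraries by group, with marker shape for replicate, a line at the mean and a bar of 1 SD. Ube3a averaged 34.6 CPM in the control, 209 in the glial line and 70.4 in the neuronal line, and w averaged 20.7, 172 and 59.6 CPM.

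The glial line was compared with the control to ask what glial Dube3a expression changes. Of 34 neuropeptide genes 6 fell and 28 did not pass, and the list had an adjusted p = 0.13 with an estimated correlation. Pdf, the neuropeptide of the clock neurons, fell from 22.8 ± 2.65 to 4.50 ± 0.625 CPM (-2.34 ± 0.17, adjusted p = 0.00023). The gene sNPF, a feeding and sleep peptide, fell from 137 ± 10.6 to 68.2 ± 4.34 CPM (-1.01 ± 0.12, adjusted p = 0.0026). The astrocyte-like glia gene alrm fell from 324 ± 60.1 to 101 ± 25.8 CPM (-1.68 ± 0.25, adjusted p = 0.0067), and Sod3, an extracellular superoxide dismutase, fell from 244 ± 31.4 to 80.6 ± 3.8 CPM (-1.60 ± 0.13, adjusted p = 0.00041). Of 34 glutathione S-transferases 8 rose, of 36 proteasome subunits 7, of 27 fat body markers 3, of 15 hemocyte markers 4 and of 55 cuticle genes 14. With an estimated correlation the lists of the proteasome (adjusted p = 0.28), hemocytes (0.31) and cuticle (0.13) did not pass. Among the genes that rose were the iron carrier gene Tsf1 (260 ± 63.7 to 833 ± 161 CPM, 1.68 ± 0.27, adjusted p = 0.01), the hemocyte clotting gene Hml (97.8 ± 8.01 to 218 ± 13.4 CPM, 1.16 ± 0.17, adjusted p = 0.0067) and the proteasome core gene Prosbeta4 (39.5 ± 0.647 to 76.1 ± 5.11 CPM, 0.94 ± 0.09, adjusted p = 0.0011). Of 11430 genes tested, 290 rose and 215 fell, 505 in all, against 2280 with an unadjusted p under 0.05. Among these calls, 177 rose and 124 fell at least 2-fold.

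The glial count moved by over 1.5 times without control 1 (181), control 2 (296), control 3 (283), glial 3 (254) or neuronal 3 (188 higher and 146 lower), with DESeq2 (1113), with a replicate block (281), with the 6 libraries alone (274) and with scaling by library totals (281). Scaling by library totals moved the median log2 fold change of all genes by -0.10 and turned the balance of calls, to 126 higher of 281.

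Glutathione S-transferases conjugate glutathione to toxic and oxidised compounds. In the glial line 8 of 34 tested members rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 1e-06; adjusted p = 0.044 with an estimated correlation). GstD5 rose by 4.04 ± 0.52 (adjusted p = 0.0037), GstD2 by 3.32 ± 0.45 (0.0048), GstE1 by 1.25 ± 0.18 (0.0058) and GstD3 by 1.02 ± 0.15 (0.0062). Of 76 cytochrome P450 genes, 9 rose and 5 fell, 15 and 6 adjusted over the list alone (median 0.19, adjusted p = 0.0084; adjusted p = 0.34 with an estimated correlation). Cyp4d1 (2.21 ± 0.23, adjusted p = 0.0016) and Cyp309a2 (2.11 ± 0.26, 0.0029) rose, and Cyp4ac3 (-1.89 ± 0.18, 0.0011) and Cyp4p1 (-0.85 ± 0.11, 0.0032) fell. The P450 call was lost without glial 1 (0.13, adjusted p = 0.108), and the median was 0.42 without control 3. Among 25 glutathione and redox enzymes, Sod3 fell and the peroxiredoxin gene Prx6c rose (0.79 ± 0.14, adjusted p = 0.017), the same 1 and 1 adjusted over the list alone (median 0.21, adjusted p = 0.44). The Prx6c call was lost without control 2, control 3, glial 2 or glial 3, with library totals and with the 6 libraries alone (adjusted p = 0.0537 to 0.0735).

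Lists of other tissues and cell types were examined in the glial line. Of 27 fat body markers, 3 rose and none fell with edgeR, 7 and 0 adjusted over the list alone (median 0.43, adjusted p = 2.1e-05; adjusted p = 0.044 with an estimated correlation). There were 10 and 0 at an unadjusted p under 0.05, 7 and 0 with DESeq2 and 3 and 0 with limma-voom. Of 15 hemocyte markers, 4 rose and none fell, 8 and 0 adjusted over the list alone (median 0.50, adjusted p = 6.3e-05; adjusted p = 0.31 with an estimated correlation). There were 8 and 0 unadjusted, 6 and 0 with DESeq2 and 4 and 0 with limma-voom. Of 55 cuticle protein genes, 14 rose and 3 fell, 18 and 3 adjusted over the list alone (median 0.69, adjusted p = 1.4e-07; adjusted p = 0.13 with an estimated correlation). Ccp84Ag (3.47 ± 0.31, adjusted p = 0.00069), Cpr72Ec (2.16 ± 0.24, 0.002) and Cpr97Ea (1.71 ± 0.23, 0.0044) were among those that rose. The gut markers had a median of 0.73 (adjusted p = 0.011; adjusted p = 0.83 with an estimated correlation), with 0 of 22 members past the threshold with edgeR and 0 adjusted over the list alone, 5 higher at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom. That gut call was lost without control 3 (0.27, adjusted p = 0.268), glial 1 (0.50, 0.147) or glial 3 (0.31, 0.116), and with the gut level as a covariate its sign turned (-0.79, 0.111). Its median was 0.41 without control 1, 2.38 without control 2 and 1.25 without glial 2. The storage protein gene Lsp2 gave 4.68 ± 1.05 (12.3 ± 9.45 to 315 ± 228 CPM, adjusted p = 0.04). This call was lost without any 1 of the 3 control or 3 glial libraries or neuronal 3, with a replicate block and with the gut level as a covariate (adjusted p = 0.0526 to 0.111). Reads of Lsp2 and of the antisense gene asRNA:CR11538 on the same stretch cannot be told apart here.

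Antimicrobial and humoral immune genes had 4 of 31 members that rose and 1 that fell, 7 and 1 adjusted over the list alone (median 0.58, adjusted p = 0.005; adjusted p = 0.37 with an estimated correlation). The immune transcription factor gene Rel (0.62 ± 0.12, adjusted p = 0.02) was among those that rose, with its call lost without control 1, control 2 or glial 3, with library totals, a replicate block and the 6 libraries alone (adjusted p = 0.0537 to 0.233). The immune list's call was lost without control 3 (0.65, adjusted p = 0.151) and with the gut level as a covariate (0.34, 0.0532), and its median was 0.27 without glial 3. Of 27 lipid metabolism genes, 2 rose and none fell with edgeR, 9 and 0 adjusted over the list alone (median 0.40, adjusted p = 6.8e-05; adjusted p = 0.12 with an estimated correlation). There were 11 and 0 unadjusted, 7 and 0 with DESeq2 and 0 and 0 with limma-voom. This list shares 8 genes with the fat body list.

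Proteasome subunits, the parts of the protease that degrades ubiquitinated proteins, had 7 of 36 members that rose and none that fell with edgeR, 20 and 1 adjusted over the list alone (median 0.46, adjusted p = 1.1e-08; adjusted p = 0.28 with an estimated correlation). At an unadjusted p under 0.05, 24 were higher and 1 lower; DESeq2 gave 12 and 1 and limma-voom 6 and 0. Heat shock and chaperone genes had 0 of 24 members that rose and 1 that fell with edgeR, 0 and 2 adjusted over the list alone, 3 and 2 unadjusted, 1 and 2 with DESeq2 and 0 and 1 with limma-voom. Their median was 0.05, their mean -0.05 and the test direction down (adjusted p = 0.86), and the median was -0.04 with library totals.

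Of 34 neuropeptide genes, 6 fell and 0 rose with edgeR, 9 and 1 adjusted over the list alone (median -0.53, adjusted p = 9.4e-06; adjusted p = 0.13 with an estimated correlation). There were 15 lower and 2 higher unadjusted, 9 and 1 with DESeq2 and 6 and 1 with limma-voom. Besides Pdf and sNPF, the adipokinetic hormone gene Akh (-1.78 ± 0.29, adjusted p = 0.011) and the diuretic hormone gene Dh31 (-1.19 ± 0.18, 0.0081) fell. Of 22 genes of neurotransmitter synthesis and transport, 2 fell and 1 rose, 6 and 1 adjusted over the list alone (median -0.25, adjusted p = 0.028; adjusted p = 0.16 with an estimated correlation), and this list call was lost without glial 1 (-0.16, adjusted p = 0.14). The acetylcholinesterase gene Ace gave -0.63 ± 0.12 (adjusted p = 0.026), lost without any 1 control library, glial 2 or glial 3, with library totals and a replicate block (adjusted p = 0.0535 to 0.0953). Of 38 neurotransmitter receptor genes, 1 fell and 0 rose with edgeR, 3 and 0 adjusted over the list alone (median -0.21, adjusted p = 0.0048; adjusted p = 0.28 with an estimated correlation). There were 8 lower and 3 higher unadjusted, 3 and 1 with DESeq2 and 1 and 0 with limma-voom. It was the dopamine receptor gene Dop1R1 (-0.81 ± 0.16, adjusted p = 0.024), lost without control 1, control 2 or glial 3, with library totals, a replicate block and the 6 libraries alone (adjusted p = 0.0542 to 0.0953). Of 29 synaptic vesicle release genes, the syntaxin gene Syx1A fell (-0.47 ± 0.11, adjusted p = 0.044), lost without any 1 of the control or neuronal libraries, glial 2 or glial 3 and in 5 other settings (adjusted p = 0.0607 to 0.195). No member of that list rose with edgeR and 0 passed adjusted over the list alone (median -0.17, adjusted p = 0.0096; adjusted p = 0.34 with an estimated correlation; median -0.26 without glial 2). There were 6 lower and 0 higher unadjusted, 3 and 0 with DESeq2 and 1 and 0 with limma-voom.

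Ion transport genes of glia and neurons moved both ways. Of 15 genes of the sodium-potassium pump and cation transport, 4 fell and 1 rose, 5 and 1 adjusted over the list alone (median -0.19, adjusted p = 0.0052; adjusted p = 0.12 with an estimated correlation). The potassium channel gene Irk3 fell by 1.5 ± 0.14 (adjusted p = 0.001), zyd, a sodium-calcium-potassium exchanger of cortex glia, fell by 1.32 ± 0.15 (0.0023), and the cation-chloride cotransporter gene Ncc69 rose by 0.97 ± 0.12 (0.0029). The pump subunit gene nrv2 also fell (-0.81 ± 0.14, adjusted p = 0.014), a call lost without control 1 (adjusted p = 0.0654) and with a replicate block (0.0526). Of 30 glial markers, 4 rose and 5 fell, 5 and 6 adjusted over the list alone (median -0.05, adjusted p = 0.68); Gli, a septate junction gene of the blood-brain barrier, rose by 0.91 ± 0.10 (adjusted p = 0.0021), while alrm and zyd fell. Of 15 pteridine and monoamine genes, 2 rose and 1 fell, 3 and 3 adjusted over the list alone (median 0.00, camera adjusted p = 0.15, and a median of -0.11 with library totals). The gene w, whose mini-white form commonly marks transgenes, is a member and was among those that rose. Pu, GTP cyclohydrolase, fell by 1.15 ± 0.13 (332 ± 13.3 to 150 ± 15.8 CPM, adjusted p = 0.0019).

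The other lists had adjusted p above 0.05 in the glial line or few members past the threshold. Mitochondrial oxidative phosphorylation had a median of -0.15 over 69 genes (adjusted p = 0.026; adjusted p = 0.83 with an estimated correlation), with 0 higher and 1 lower with edgeR and the same adjusted over the list alone, 0 and 3 unadjusted, 0 and 2 with DESeq2 and 0 and 1 with limma-voom. That call was lost without control 2 (-0.16, adjusted p = 0.0815), glial 1 (-0.02, 0.844) or glial 2 (-0.13, 0.0667) and with no low-count filter (-0.14, 0.0581), and the median was -0.30 without glial 3. Medians were -0.08 for 25 voltage-gated channels (adjusted p = 0.15), -0.08 for 23 neuronal markers (0.15), -0.41 for 23 chemosensory markers (0.55), -0.02 for 87 ribosomal proteins (0.52) and 0.10 for 21 glycolysis genes (0.39). They were 0.03 for 30 eye markers (adjusted p = 0.6), -0.03 for 27 muscle markers (0.49), -0.01 for 12 sex-linked markers (0.87) and 0.01 for 14 clock genes (0.15). The mean and median differed in sign for muscle (mean 0.06), sex-linked (mean 0.13) and clock genes (mean -0.19). With library totals the medians of eye markers (-0.08), clock genes (-0.08) and glycolysis (-0.04) turned negative. Counts over all genes tested and adjusted over the list alone were alike for neuronal markers (1 lower), muscle (TpnC73F lower), clock genes (Pdf lower) and eye markers (ninaD higher, 1 lower). Of the chemosensory markers 1 was lower over all genes and 0 adjusted over the list alone. With edgeR 0 passed either way among voltage-gated channels (3 lower unadjusted, 1 with DESeq2, 0 with limma-voom) and ribosomal proteins (3 higher and 7 lower unadjusted, 4 lower with DESeq2, 0 with limma-voom). The same held for sex-linked markers (1 higher unadjusted, 1 with DESeq2, 0 with limma-voom) and glycolysis (5 higher and 1 lower unadjusted, 3 higher with DESeq2, 0 with limma-voom). The carotenoid uptake gene ninaD rose by 2.65 ± 0.32 (adjusted p = 0.0029), and the muscle calcium-binding gene TpnC73F fell by 1.07 ± 0.17 (0.0091).

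Single genes with the largest changes in the glial line included several with hardly any counts on one side. CG3397 held 1 count in the glial libraries against 1613 in the control, a ratio of 1900 with a 95% counting interval of 340 to 75000. CG9377 held 3 against 1461 counts, a ratio of 573 (196 to 2780). CG10514 (-4.50 ± 0.27, adjusted p = 0.00012), the photolyase gene phr (-4.02 ± 0.37, 0.00075), the gap gene gt (-4.03 ± 0.48, 0.0025) and the pigment gene y (-3.69 ± 0.37, 0.0011) fell. The cytokine gene upd3, a ligand of JAK/STAT signalling, rose by 4.74 ± 0.70 (0.0373 ± 0.0325 to 1.04 ± 0.205 CPM, adjusted p = 0.0067), and AOX2, an aldehyde oxidase gene, rose by 4.55 ± 0.57 (adjusted p = 0.0032). CG32437 had 0 control counts and 207 glial counts, at least 58.6-fold higher, with its call lost without glial 3 (adjusted p = 0.0592) and with a replicate block (0.0796).

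**Figure D2:**
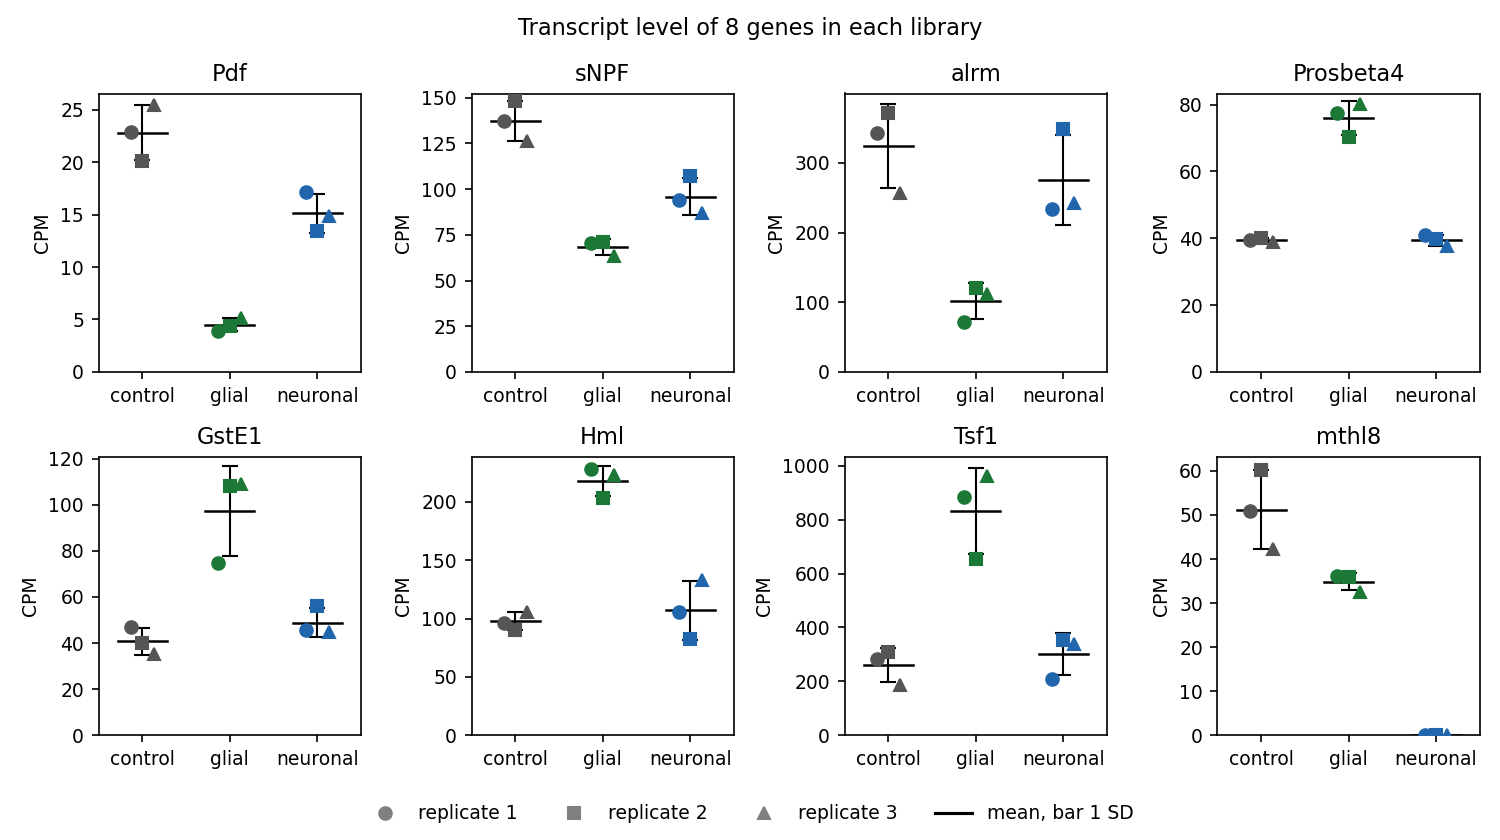
CPM of 8 genes in each of the 9 libraries by group, on linear axes from 0, with marker shape for replicate, a line at the mean and a bar of 1 SD. Pdf, sNPF and alrm were lower and Prosbeta4, GstE1, Hml and Tsf1 higher in the glial line than in the control, and mthl8 averaged 0.0596 CPM in the neuronal line against 51.2 in the control.

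The neuronal line was compared with the control to ask what neuronal Dube3a expression changes. The clearest differences were in single genes: mthl8, a member of the methuselah-like receptor family, fell from 51.2 ± 8.97 to 0.0596 ± 0.0434 CPM (-9.74 ± 0.34, adjusted p = 3.6e-06). The peroxiredoxin gene Prx6b fell from 51.7 ± 13.3 to 9.77 ± 0.144 CPM (-2.40 ± 0.22, adjusted p = 0.0034). The stress peptide gene TotM fell by 2.36 ± 0.24 (adjusted p = 0.0054) and the photolyase gene phr fell by 3.42 ± 0.36 (0.0058), while Cyp4d1, a P450 gene, rose by 2.11 ± 0.23 (0.0071). CG3397 had 0 neuronal counts against 1613 in the control, at least 590-fold lower, and Reepl1 had 0 control counts against 959 in the neuronal libraries, at least 291-fold higher, a call lost with a replicate block (adjusted p = 0.0628). The noncoding gene lncRNA:CR45284 rose by 5.58 ± 0.59 (adjusted p = 0.0061). The cuticle gene Ccp84Ag rose by 2.41 ± 0.30 (adjusted p = 0.0098), a call lost without neuronal 3 (adjusted p = 0.0577). Of 11430 genes tested, 35 rose and 46 fell, 81 in all, against 1518 with an unadjusted p under 0.05. Among these calls, 33 rose and 33 fell at least 2-fold.

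The neuronal count moved by over 1.5 times without control 1 (28), control 2 (47), control 3 (41), glial 2 (52), neuronal 1 (33), neuronal 2 (26) or neuronal 3 (16), with DESeq2 (470), a replicate block (15), the stricter filter (46) and library totals (44). Scaling by library totals turned the balance of calls, to 27 higher and 17 lower.

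In the neuronal line 12 of 28 lists passed with the preset correlation. With an estimated correlation 0 passed, the smallest adjusted p being 0.56, and 0 passed with fry. Neuronal markers had a median of 0.27 (adjusted p = 0.00024; adjusted p = 0.56 with an estimated correlation), with 0 of 23 members past the threshold with edgeR, 4 higher adjusted over the list alone, 8 higher unadjusted, 4 with DESeq2 and 0 with limma-voom. The cytoskeletal gene futsch gave 0.62 ± 0.21 (adjusted p = 0.27). Cytosolic ribosomal proteins had a median of -0.22 over 87 genes (adjusted p = 0.00024; adjusted p = 0.64 with an estimated correlation), -0.14 without control 1. None of them passed with edgeR and 0 did adjusted over the list alone; 13 were lower unadjusted, 2 with DESeq2 and 0 with limma-voom. Of 55 cuticle genes, 2 rose and 1 fell, 12 and 4 adjusted over the list alone (median 0.41, adjusted p = 0.00087; adjusted p = 0.56 with an estimated correlation). Of 31 immune genes, TotM fell and 0 rose with edgeR, 4 and 1 adjusted over the list alone (median -0.31, adjusted p = 0.0016; adjusted p = 0.56 with an estimated correlation), with 9 lower and 2 higher unadjusted, 5 and 2 with DESeq2 and 1 and 0 with limma-voom. The median was -0.15 without control 1, -0.60 without control 3 and -0.59 without neuronal 2. Of 25 redox enzymes, Prx6b and Sod3 fell and 0 rose with edgeR, 6 and 1 adjusted over the list alone (median -0.13, adjusted p = 0.0066; adjusted p = 0.56 with an estimated correlation), with 7 lower and 1 higher unadjusted, 5 and 0 with DESeq2 and 2 and 0 with limma-voom. Sod3 gave -0.75 ± 0.13 (adjusted p = 0.044), a call lost without any 1 of the 9 libraries and in 5 other settings (adjusted p = 0.0552 to 0.261).

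Neurotransmitter receptors had a median of 0.18 in the neuronal line (adjusted p = 0.0051; adjusted p = 0.56 with an estimated correlation), with 0 of 38 members past the threshold with edgeR, 1 higher adjusted over the list alone, 8 higher and 1 lower unadjusted, 2 and 0 with DESeq2 and 0 with limma-voom. The nicotinic receptor gene nAChRbeta1 gave 0.40 ± 0.13 (adjusted p = 0.21). Voltage-gated channels had a median of 0.20 (adjusted p = 0.015; adjusted p = 0.64 with an estimated correlation) and synaptic vesicle release 0.15 (0.039; adjusted p = 0.64 with an estimated correlation). Both calls were lost without control 2 (0.16, adjusted p = 0.0591, and 0.15, 0.0763), control 3 (0.19, 0.0739, and 0.13, 0.118) or neuronal 2 (0.15, 0.142, and 0.07, 0.145). Neuropeptides had a median of -0.18 (adjusted p = 0.012; adjusted p = 0.56 with an estimated correlation), lost without control 3 (-0.15, 0.0636) or neuronal 3 (-0.12, 0.116), and -0.29 without control 2 and -0.30 without neuronal 1. Oxidative phosphorylation had a median of -0.15 (adjusted p = 0.0044; adjusted p = 0.65 with an estimated correlation). Sex-linked markers had a median of -0.60 (adjusted p = 0.0094; adjusted p = 0.56 with an estimated correlation), lost without neuronal 1 (-0.48, 0.0638), and -0.38 without control 1. Gut markers had a median of 0.74 (adjusted p = 0.0017; adjusted p = 0.64 with an estimated correlation), lost without control 3 (0.21, 0.15), with 0.44 without control 1, 2.55 without control 2, 1.2 without neuronal 1 and 0.03 without neuronal 2. With edgeR 0 members of these 6 lists passed. Adjusted over the list alone 2 neuropeptides were lower and 0 members of the other 5 lists passed, and limma-voom gave 0 in each. Unadjusted counts higher and lower were 2 and 0 for channels, 5 and 1 for vesicle release, 1 and 8 for neuropeptides, 0 and 5 for oxidative phosphorylation, 0 and 4 for sex-linked and 1 and 0 for gut markers. DESeq2 gave 0 and 0, 1 and 1, 0 and 4, 0 and 1, 0 and 2, and 0 and 0. With the yolk protein level as a covariate the calls of channels (0.18, adjusted p = 0.0503), vesicle release (0.17, 0.0503), neuropeptides (-0.20, 0.0829), oxidative phosphorylation (-0.05, 0.399), sex-linked markers (-0.08, 0.094) and ribosomal proteins (-0.08, 0.0503) were lost. With the gut level as a covariate those of neuropeptides (-0.11, 0.0908) and gut markers (-0.47, 0.122) were lost, the latter with its sign turned. In the same line, the fat body median was -0.11 (mean 0.12, adjusted p = 0.85), the glutathione S-transferase median 0.13 (adjusted p = 0.28) and the proteasome median -0.05 (adjusted p = 0.41; 0.01 with library totals).

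**Figure D3:**
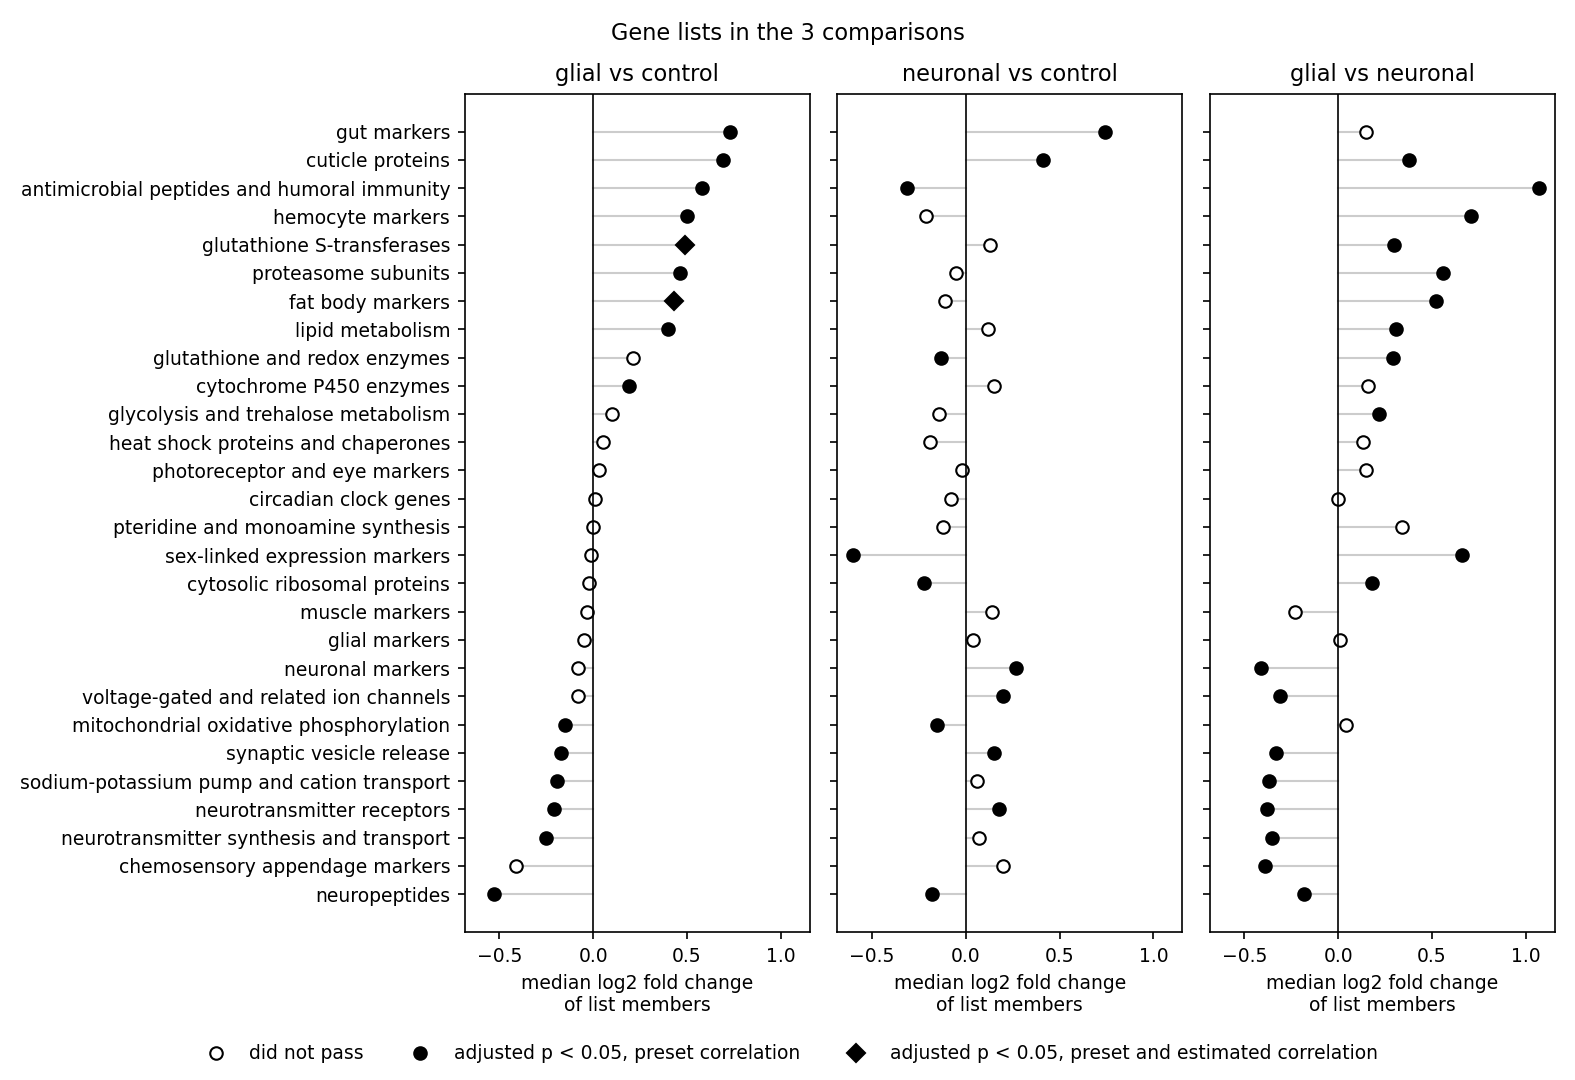
Median log2 fold change of the members of each of 28 gene lists in the 3 comparisons, filled where the camera adjusted p was under 0.05 and as a diamond where that held with an estimated correlation too. Scaling by library totals turned the sign of 12 medians, among them P450 enzymes and oxidative phosphorylation in glial against neuronal.

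The driver lines were compared with each other, which tests a difference between the lines, the drivers included. Pdf was lower in the glial than in the neuronal line (4.50 ± 0.625 against 15.1 ± 1.89 CPM, -1.75 ± 0.17, adjusted p = 0.00089). So were the dopamine receptor gene Dop1R1 (28.2 ± 5.15 against 66.4 ± 5.79 CPM, -1.24 ± 0.16, 0.0042) and zyd (19.9 ± 3.32 against 51.4 ± 5.43 CPM, -1.37 ± 0.15, 0.0023). Prosbeta4 was higher in the glial line (76.1 ± 5.11 against 39.4 ± 1.71 CPM, 0.95 ± 0.09, adjusted p = 0.0012). So were the malic enzyme gene Men (1040 ± 168 against 482 ± 48.9 CPM, 1.10 ± 0.17, 0.0094), the scavenger receptor gene Sr-CI (15.1 ± 3.67 against 4.85 ± 0.0846 CPM, 1.64 ± 0.18, 0.0024) and Gnmt, glycine N-methyltransferase (90.2 ± 32.9 against 5.17 ± 1.58 CPM, 4.13 ± 0.35, 0.00057). GstD3 (1.54 ± 0.15, adjusted p = 0.001) and GstD5 (4.04 ± 0.52, 0.0042) were higher too, and Sod3 (-0.85 ± 0.13, 0.0094) and Pu (-0.91 ± 0.13, 0.0061) lower. Of 11430 genes, 231 were higher and 191 lower in the glial line, 422 in all, against 2077 with an unadjusted p under 0.05. Among these calls, 130 were higher and 94 lower by at least 2-fold.

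The count between the driver lines moved by over 1.5 times without control 1 (262), glial 3 (177), neuronal 1 (154), neuronal 2 (207) or neuronal 3 (193), with DESeq2 (1013), a replicate block (241), the 6 libraries alone (227) and library totals (243). Scaling by library totals moved the median of all genes by -0.15 and turned the balance of calls, to 95 higher and 148 lower.

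Nervous system lists were lower in the glial than in the neuronal line with the preset correlation and did not pass with an estimated one. Of 38 neurotransmitter receptors, 7 were lower and 1 higher, 20 and 1 adjusted over the list alone (median -0.38, adjusted p = 5e-09; adjusted p = 0.057 with an estimated correlation). Of 23 neuronal markers, 4 were lower and 0 higher with edgeR, 12 and 0 adjusted over the list alone (median -0.41, adjusted p = 3.2e-07; adjusted p = 0.15 with an estimated correlation), with 15 and 0 unadjusted, 8 and 0 with DESeq2 and 3 and 0 with limma-voom. Of 29 synaptic vesicle release genes, 2 were lower and 0 higher with edgeR, 8 and 0 adjusted over the list alone (median -0.33, adjusted p = 1.6e-06; adjusted p = 0.1 with an estimated correlation), with 15 and 1 unadjusted, 7 and 0 with DESeq2 and 2 and 0 with limma-voom. Medians were -0.31 for voltage-gated channels (adjusted p = 9.9e-05; adjusted p = 0.32 with an estimated correlation) and -0.37 for the sodium-potassium pump list (adjusted p = 0.00052; adjusted p = 0.061 with an estimated correlation). Neurotransmitter synthesis had a median of -0.35 (adjusted p = 0.0077; adjusted p = 0.1 with an estimated correlation), lost without glial 1 (-0.30, 0.0594) and -0.22 without neuronal 2. Neuropeptides had a median of -0.18 (adjusted p = 0.012; adjusted p = 0.28 with an estimated correlation), lost without glial 1 (-0.20, 0.126) or neuronal 1 (0.00, 0.061) and -0.31 without neuronal 3. Chemosensory markers had a median of -0.39 (adjusted p = 0.019; adjusted p = 0.56 with an estimated correlation), lost without neuronal 1 (0.00, 0.289), with library totals (-0.55, 0.074) and with the stricter filter (-0.27, 0.118). Members lower and higher over all genes were 1 and 0 for channels, 3 and 1 for the pump list, 4 and 0 for neurotransmitter synthesis, and 1 and 0 for neuropeptides (Pdf) and for chemosensory markers. Adjusted over the list alone they were 6 and 0, 6 and 1, 7 and 1, 4 and 0, and 1 and 0. The markers of glia had a median of 0.01, a mean of -0.05 and a test direction down (adjusted p = 0.44), with a median of -0.16 under library totals.

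Immune, hemocyte, fat body and proteasome lists were higher in the glial than in the neuronal line with the preset correlation and did not pass with an estimated one. Of 31 immune genes, 8 were higher and 0 lower with edgeR, 15 and 0 adjusted over the list alone (median 1.07, adjusted p = 8.4e-10; adjusted p = 0.1 with an estimated correlation), with 17 and 1 unadjusted, 15 and 0 with DESeq2 and 7 and 0 with limma-voom. Of 15 hemocyte markers, 6 were higher and 0 lower with edgeR, 9 and 0 adjusted over the list alone (median 0.71, adjusted p = 8.4e-10; adjusted p = 0.1 with an estimated correlation), with 9 and 0 unadjusted, 9 and 0 with DESeq2 and 6 and 0 with limma-voom. Of 36 proteasome genes, 9 were higher and 0 lower with edgeR, 22 and 0 adjusted over the list alone (median 0.56, adjusted p = 1.7e-12; adjusted p = 0.15 with an estimated correlation), with 24 and 0 unadjusted, 18 and 0 with DESeq2 and 9 and 0 with limma-voom. Of 27 fat body markers, 4 were higher and 0 lower with edgeR, 8 and 1 adjusted over the list alone (median 0.52, adjusted p = 2e-05; adjusted p = 0.057 with an estimated correlation), with 11 and 1 unadjusted, 7 and 0 with DESeq2 and 4 and 1 with limma-voom. Glutathione S-transferases had a median of 0.30 (adjusted p = 2e-05; adjusted p = 0.057 with an estimated correlation; 0.49 without glial 2 and 0.47 without neuronal 2), and redox enzymes 0.29 (adjusted p = 0.00055; adjusted p = 0.18 with an estimated correlation). Members higher and lower were 4 and 0 for the transferases and 3 and 1 for the redox enzymes, 10 and 1 and 3 and 1 adjusted over the list alone. Lipid metabolism had a median of 0.31 (adjusted p = 0.004; adjusted p = 0.1 with an estimated correlation), with 0 of 27 past the threshold with edgeR, 7 higher and 2 lower adjusted over the list alone, 10 and 2 unadjusted, 6 and 1 with DESeq2 and 1 and 1 with limma-voom.

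The remaining lists that passed between the driver lines all lost their call without glial 3 or another library. Cuticle genes had a median of 0.38 (adjusted p = 0.008; adjusted p = 0.33 with an estimated correlation), 0.16 without glial 3 (adjusted p = 0.0892). Ribosomal proteins had a median of 0.18 (adjusted p = 0.0071; adjusted p = 0.52 with an estimated correlation), 0.07 without glial 3 (0.249) and 0.27 without glial 1. Glycolysis genes had a median of 0.22 (adjusted p = 0.012; adjusted p = 0.43 with an estimated correlation), 0.05 without glial 3 (0.126). Sex-linked markers had a median of 0.66 (adjusted p = 0.013; adjusted p = 0.18 with an estimated correlation), lost without glial 2 (0.45, 0.057) or neuronal 1 (0.52, 0.0609), with 1.08 without glial 1 and 0.34 without glial 3. With the yolk protein level as a covariate the calls of cuticle (0.20, adjusted p = 0.0613), ribosomal (0.11, 0.162), sex-linked (0.05, 0.0613) and chemosensory (-0.22, 0.0576) lists were lost, and with the stricter filter that of cuticle genes (0.26, 0.0592). With limma-voom that of sex-linked markers was lost (0.47, 0.0637). Members higher and lower were 3 and 2 for cuticle genes, 1 and 0 for glycolysis and 2 and 0 for sex-linked markers, 8 and 4, 1 and 0, and 4 and 0 adjusted over the list alone. No ribosomal protein gene passed with edgeR, and 0 did adjusted over the list alone, with 5 higher unadjusted, 1 with DESeq2 and 0 with limma-voom. P450 enzymes had a median of 0.16 (adjusted p = 0.1), which was -0.02 with library totals.

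**Figure D4:**
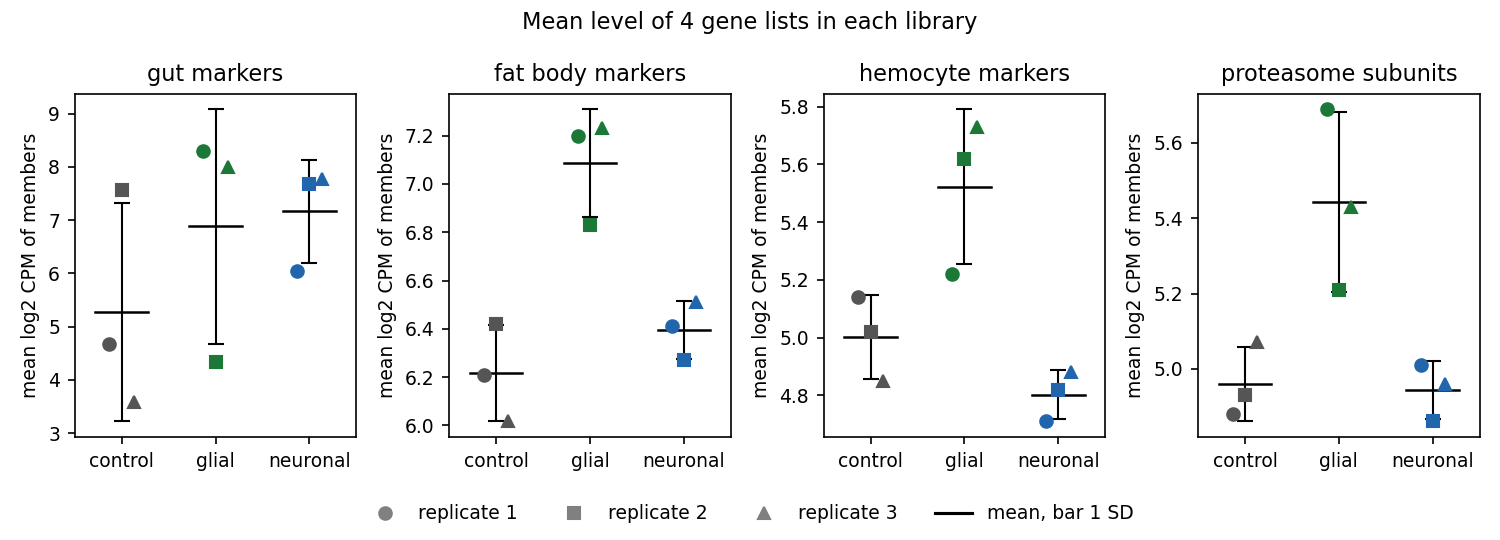
Mean log2 CPM of the members of 4 gene lists in each of the 9 libraries by group, with marker shape for replicate, a line at the mean and a bar of 1 SD, on a separate scale for each list. Fat body levels were 7.2, 6.83 and 7.23 in glial libraries 1, 2 and 3, above the 6 other libraries, while gut levels ranged from 3.58 to 8.30 with no order by group.

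Of the genes that passed against the control, 20 rose in both lines and 20 fell in both, 40 in all, where independent lists would share 1.80. The 20 that rose include Ube3a, the gene of the transgene, and w, whose mini-white form commonly marks transgenes. The genes CG13705 (2.52 ± 0.30 glial, 2.64 ± 0.30 neuronal), Cyp4d1 and w rose in both, and phr and CG3397 fell in both; the neuronal call of CG13705 was lost with a replicate block (2.62, adjusted p = 0.0501). Both comparisons used the same 3 control libraries, which raises the overlap, and 3 libraries cannot be split between them. In simulations with no effects and shared controls, the highest number of genes called in both was 0. Real effects beside shared controls were not simulated, so how much of the 40 comes from the shared controls was not measured. The covariance of the log2 fold changes across genes was 0.221, against a mean of 0.087 and a highest of 0.098 in 50 simulations with no effects and shared controls. These simulations drew each gene independently, without structure shared across genes within a library such as the gut level. Such structure in the shared controls can raise the covariance, so the excess does not show shared effects. Pearson's r across genes, which are not independent replicates, was 0.53 (Spearman's rho 0.48), against 0.50 on average and 0.54 at most in the simulations. The same sign was seen in 67.1% of genes, against 66.8%. The count of 40 was 14 without control 1, 22 without control 2, 19 without control 3, 25, 24 and 26 without glial 1, 2 and 3, 19, 15 and 10 without neuronal 1, 2 and 3, 9 with a replicate block, 22 with the 6 compared libraries alone, 26 with the gut level as a covariate and 188 with DESeq2. With library totals it was 22, of which 17 rose and 5 fell. The covariance was 0.617 without control 2, 0.822 with no low-count filter and 0.122 with the stricter filter, with a jackknife standard error of 0.313. CG9616 changed in opposite directions (1.12 ± 0.30 CPM in the control, 4.33 ± 1.27 glial, 0.0942 ± 0.0276 neuronal), by 1.94 ± 0.31 (adjusted p = 0.0097) and -3.51 ± 0.39 (adjusted p = 0.0071), the latter lost without neuronal 3 (adjusted p = 0.052) and with limma-voom (0.0686).

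**Figure D5:**
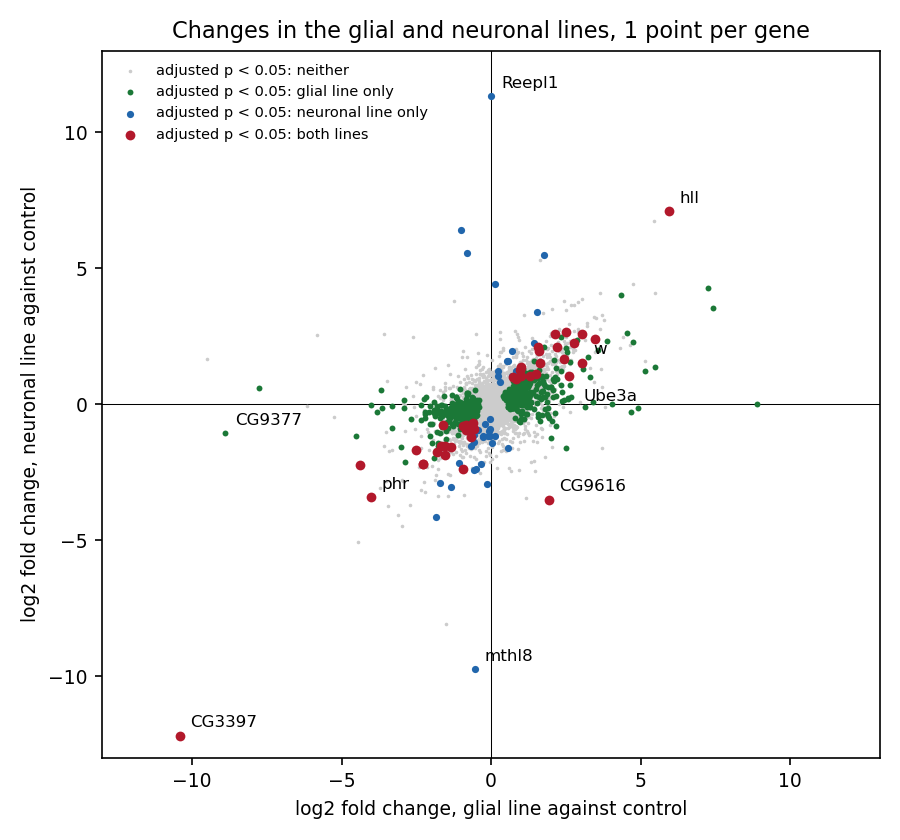
Log2 fold change against the control in the glial line (horizontal axis) and the neuronal line (vertical axis), 1 point per tested gene, coloured by the line in which the adjusted p was under 0.05. The 40 genes that changed in one direction in both lines lie in the lower left and upper right, and CG9616 lies in the lower right.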

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

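The comparison of Lsp2 and Tsf1 with other fat body markers, the comparison of tissue lists over libraries, the share of neuronal calls changed less in the glial line and the alternatives with a covariate were chosen after the results were seen.

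For 13 lists the median against the control had opposite signs in the glial and neuronal lines and the camera test between the lines passed with the preset correlation. Against the control, the preset test passed in both lines only for immune genes, synaptic vesicle release and neurotransmitter receptors, none of them with an estimated correlation. For each of the other lists the value of the glial line, the neuronal line or both did not pass, so opposite changes were not shown. The fat body mean in the neuronal line was 0.12, against a negative median. The glial minus neuronal medians were 0.29 for redox enzymes (0.21 glial, -0.13 neuronal against control), 1.07 for immune genes (0.58, -0.31), 0.52 for fat body (0.43, -0.11) and 0.71 for hemocytes (0.50, -0.21). They were 0.56 for the proteasome (0.46, -0.05) and 0.22 for glycolysis (0.10, -0.14; with library totals the glial value was -0.04 and the neuronal proteasome value 0.01). They were -0.37 for the sodium-potassium pump list (-0.19, 0.06), -0.31 for voltage-gated channels (-0.08, 0.20), -0.33 for synaptic vesicle release (-0.17, 0.15), -0.35 for neurotransmitter synthesis (-0.25, 0.07) and -0.38 for neurotransmitter receptors (-0.21, 0.18). They were -0.41 for neuronal markers (-0.08, 0.27) and -0.39 for chemosensory markers (-0.41, 0.20). With an estimated correlation the adjusted p of these 13 differences ran from 0.057 to 0.56, so none passed. Calls were lost without glial 1 for neurotransmitter synthesis (-0.30, adjusted p = 0.0594), without glial 3 for glycolysis (0.05, 0.126) and without neuronal 1 for chemosensory markers (0.00, 0.289). The gene CG9616 differed by 5.45 ± 0.39 between the lines (1.94 glial, -3.51 neuronal against control; adjusted p = 0.00045 for the difference), with its neuronal call lost without neuronal 3 (adjusted p = 0.052).

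The level of gut markers ranged 26.4-fold between libraries, from control 3 to glial 1, and also varied among libraries of one genotype. Gut tissue carried into some samples may account for it: over the 9 libraries the median pairwise Pearson r of 22 gut markers was 0.81, above the bound of 0.8 set beforehand, while the highest of 1000 random lists gave 0.19. Genes regulated together would give a high r too, and random lists do not part these cases, so this does not settle the source. The most abundant members, betaTry and Jon99Ciii, averaged 7200 and 5060 CPM in the control, and dissection of brains would leave that tissue out. No biological explanation was tested, since the design gives none, and genotype accounted for 23.8% of the variance (exact permutation p = 0.47). With the gut level as a covariate 367 genes passed in glial against control, 57 in neuronal against control and 482 between the lines.

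Strongly changed single genes, such as mthl8 in the neuronal line and CG3397 in both, may reflect sequence differences between the genotypes, those carried with the drivers among them. For genes changed in both, they may also reflect the level of Dube3a. Both lines were compared with the same control, so a difference on the control's side would appear in both, and it was not tested. Calls of the neuronal line lay on chromosome X, which carries elav, in 7 of 81 cases (8.64%, against 16.2% of tested genes; odds ratio 0.486, 95% interval 0.189 to 1.06, two-sided Fisher's exact p = 0.069), and calls of the glial line lay on chromosome 3, which carries repo, in 235 of 499 (odds ratio 1.12, 0.93 to 1.34, p = 0.23). Both intervals include 1, the other chromosomes of the lines can differ too, and no driver line without the transgene was sequenced, so neither source can be excluded. A level of Dube3a transcript that alone set the size of the change would leave no smaller change in the glial line, where Ube3a is higher. Yet, with Ube3a left out, 31.2% of neuronal calls (25 of 80, exact Clopper-Pearson interval 21.3% to 42.6%) had a glial change under 0.5 of the neuronal one and passed between the lines. Among them was mthl8 (-0.55 ± 0.21 glial, -9.74 neuronal). For these genes the values argue against that level as the only cause. All 80 were selected for a neuronal change, which raises the share. An effect of a driver could also lie over one of Dube3a, so a part played by the level is not excluded. A level acting within neurons alone was not tested. For the genes changed in both lines as a set, the level of Dube3a stays open as a cause, though TotM (-0.95 glial, -2.36 neuronal) is also among the 25 above. Of this set, with Ube3a left out, 51.3% moved further in the glial line (20 of 39, interval 34.8% to 67.6%), below the 90% predicted for that cause. The interval includes the bound of 60% for the contrary case, and the set is selected for a large neuronal change, which lowers the share.

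Fat body, hemocyte and cuticle lists were higher in the glial line, the last 2 not with an estimated correlation (camera adjusted p = 0.31 and 0.13). The cuticle list was higher in the neuronal line too (median 0.41, camera adjusted p = 0.00087, or 0.56 with an estimated correlation), so its rise was not particular to the glial line. A larger share of fat body tissue in the glial samples may account for part of the glial values. Of the 10 most abundant fat body markers outside the sex-dependent ones the lower quartile was 0.32, above the bound of 0.3 set beforehand. But 3 of the 10 passed, and 9 and not all 10 were above 0 (Apoltp gave 0.00 ± 0.17), which leaves a larger share of fat body tissue open. Tsf1 and Lsp2 exceeded the median of the other 8 by 1.29 and 4.29, but they were picked as the largest after the results were seen, so this excludes nothing. A lower share of nervous tissue would raise other tissues alike. Where fat body had a median of 0.43, resampling genes gave chemosensory markers -0.41 (-0.58 to -0.07), muscle -0.03 (-0.12 to 0.16) and eye 0.03 (-0.12 to 0.21). The first and second met the bound set beforehand. But the chemosensory and eye lists hold genes of sensory neurons, which a lower share of nervous tissue need not raise, so they cannot decide this. Genes of the chemosensory, muscle and eye lists also move together (estimated correlations 0.516, 0.207 and 0.282), and the resampling intervals ignore the spread between libraries. Over libraries, fat body minus chemosensory, muscle, eye and hemocyte levels changed by 0.97 (Welch interval -4.09 to 6.04, 95% over the 4 lists), 0.99 (-0.77 to 2.76), 0.77 (-0.54 to 2.08) and 0.34 (-1.11 to 1.80). None of these intervals lay above 0, so a lower share of nervous tissue stays open. Remains of larval fat body stay open, as does a response to glial Dube3a, which the design cannot part from the driver: 1 of 4 larval serum protein genes rose, Lsp2, and Lsp1gamma gave 0.02 ± 1.2, but Lsp1alpha had too few counts to be tested and Lsp1beta gave 1.24 ± 0.57, so the bound of fewer than 2 set beforehand excludes nothing.

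Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many genes as the real split. The real and the highest other counts were 505 and 214 for glial against control, 81 and 11 for neuronal against control, and 422 and 0 between the lines. At an unadjusted p under 0.05 the real split between the lines gave 2077 genes, with 1013 past the threshold with DESeq2 and 436 with limma-voom. The split with 214 genes set control 1, control 3 and glial 2, the libraries with low gut level, against the others, which points to a structure of the samples that follows the gut level.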

How the results depend on the processing

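The gut and yolk covariates, leaving out ribosomal RNA and yolk genes, and single transcripts were chosen after the results were seen.

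Counts of changed genes moved with the test, the threshold and the libraries used. DESeq2 gave 1113 genes for glial against control, 470 for neuronal against control and 1013 between the lines, holding 502, 81 and 422 of the genes found with edgeR, and 188 changed in one direction in both lines. Library totals alone gave 281 (126 higher; 259 shared), 44 (27 higher; 37 shared) and 243 (95 higher; 220 shared), with 22 in both lines (17 higher, 5 lower) and medians shifted by -0.10, 0.06 and -0.15. The signs of 12 list medians turned with this scaling. Using the 6 compared libraries alone gave 274 and 227 for the comparisons with the glial line and 22 in both lines. A replicate block gave 281, 15 and 241, with 9 in both lines; same-numbered libraries had r from -0.57 to 0.37 across genes, so the numbers do not appear to pair libraries. A 2-fold minimum left 301 and 224 for the comparisons with the glial line, and an adjusted p of 0.01 left 161, 23 and 132. The stricter filter left 46 for neuronal against control. The cause of these differences was not tested.

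Other settings stayed within 1.5 times of the counts: limma-voom 451, 61 and 436, DESeq2 size factors 503, 79 and 419, the gut covariate 367, 57 and 482, the yolk covariate 636, 73 and 419, ribosomal RNA and yolk genes left out 495, 77 and 435, and single transcripts 576, 100 and 517. The gut covariate left 26 genes in both lines. Leaving out 1 library gave 181 (without control 1) to 447 for glial against control, 16 (without neuronal 3) to 62 for neuronal against control, 154 (without neuronal 1) to 392 between the lines and 10 to 26 in both lines.

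Ube3a in the glial line stayed between 2.48 and 2.70 with a highest adjusted p of 0.0011. In the neuronal line it ranged from 0.94 to 1.13 without 1 library, and its call ended with library totals (1.08, adjusted p = 0.0839) and the block (1.02, 0.0501). The covariance of the 2 sets of log2 fold changes was 0.822 without a filter, 0.122 with the stricter filter and 0.240 to 0.617 without 1 library (0.617 without control 2), with a jackknife standard error of 0.313.

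List tests passed 11 to 16, 10 to 14 and 16 to 22 times without 1 library. An estimated correlation left 2, 0 and 0, and fry 12, 0 and 15. The gut list turned to -0.79 and -0.47 in the lines against control under the gut covariate, which removes its level by construction. Oxidative phosphorylation between the lines, which did not pass (0.04, camera adjusted p = 0.86), turned to -0.13 without glial 3 and passed there (adjusted p = 0.0344). Its median ranged up to 0.17 (without glial 1). The change of repo in the neuronal line, which did not pass, was -0.32 without neuronal 2 and turned to 0.06 without neuronal 1, 0.05 without neuronal 3 and 0.09 with the yolk covariate.

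Of 195 named-gene calls 86 passed under every refit per gene, the stricter thresholds and single transcripts not included (48 of 77, 8 of 36 and 30 of 82), and of 46 list calls 27 (10 of 15, 5 of 12 and 12 of 19) when the estimated correlation and fry, which left fewer, are set aside.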

Other observations

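Calls were also seen in pairs of genes that overlap on the chromosome, such as Lsp2 with an antisense transcript and phr with Prosalpha1, and reads of such a pair cannot be assigned to either gene here, as the handling of strand is not given in the sources used here.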
